A study of Drosophila melanogaster with 2 samples.

How the data were processed

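The series holds 2 ChIP-seq libraries from whole Drosophila melanogaster embryos aged 0 to 24 h that express a seq-eGFP fusion, precipitated with an anti-GFP antibody after sonication, per the labels. The labels number them as biological replicates 1 and 2 of 1 group, with separate biological samples, and this number was used to name them. The control library that the authors used for peak calling was not analysed here, and reads were not used here. The peak caller, aligner and their versions were not given in the sources used here.

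The authors deposited 4 thresholded peak lists and their 4 ranked lists, all on dm6 per the text files deposited with them: one pair for each replicate, one from pooled replicates and one called conservative. Each replicate's lists were made from that library's own alignments and 1 control alignment, and the series-wide lists from both libraries with that control. The thresholded lists also had a further input, whose nature was not stated in the sources used here. In the thresholded lists the authors' score of each peak rises as its irreproducible discovery rate (IDR) falls, and no score was under 830. In the ranked lists the authors give each peak's global IDR as -log10, capped at 5, and the highest IDR of a thresholded peak was 0.01 when rounded. The signal of a peak is the value given by the authors' peak caller, run with that control, and no rescaling between libraries is stated in the deposited files. It was used to describe and rank peaks within a list, and replicate signals were compared only as a ratio relative to other peaks. Another 8 columns of each ranked list were not used. Read depth is unknown, so no floor or interval that needs it is given, and intervals on shares and densities of peaks cover counting error only.

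Positions were set against the Drosophila genome Release 6 and the Ensembl BDGP6.54 annotation, release 115, leaving out transposable elements. Every peak and gene end lay within the reference lengths of the 7 arms 2L, 2R, 3L, 3R, 4, X and Y, and peaks elsewhere were left out (1 of the conservative set). Coordinates are counted from 1. A promoter peak had its summit within 500 bp of the TSS of any transcript. Summits were classed in the order promoter, 5' untranslated region, coding exon, 3' untranslated region, noncoding exon, intron and intergenic, and were set against 100 seeded random placements on the same arm outside assembly gaps. Overlap of replicates needed 1 bp, with a chance level from 100 seeded shuffles with bedtools 2.31.1. Intervals are exact (Clopper-Pearson for shares, Poisson for densities), and the limit given for a count of 0 is 3 counts of the total. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

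Gene lists were tested with two-sided Fisher's exact tests of members with a promoter peak against all other protein-coding genes, adjusted by Benjamini-Hochberg over 17 lists. The lists were axon and dendrite guidance, proneural and neuroblast, Notch pathway and E(spl) complex, neuronal identity transcription factors, pan-neuronal, glial, mesoderm and muscle, endoderm and fat body, tracheal and epidermal, segmentation, Hox, cytoplasmic ribosomal protein, heat shock, adult eye, adult gonad, Polycomb and Trithorax, and insulator genes. Of their members only Hsromega and calypso were not matched to a protein-coding gene. The listed Dl and Z4 had first been matched through shared synonyms to dorsal and br, and were corrected to Delta and pzg after results had been seen, which raised the insulator list from 6 to 7 members with a peak. Some genes belong to more than 1 list. The 20 fixed motifs were sought on both strands in 101 bp around each summit, against 5 control windows per peak. Controls of promoter peaks lay at the same offset from a TSS of a gene without a peak within 1000 bp, and others at random on the arm, over 500 bp from any TSS and over 1000 bp from any summit. For 6-mers, reverse complements were merged, words were found on 2L, 2R and X, and were tested again on 3L, 3R and 4. Differences of median signal were tested by permuting peak labels 100000 times.

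Genes are named by a rule fixed in advance: seq, the 20 protein-coding genes with the strongest promoter peaks, the 3 members of each list with the strongest promoter peak, and the 5 strongest peaks over 2000 bp from any TSS. The other list members, the peaks at ush, Lk6 and larp, and nSyb were chosen after their values were seen. The lists, motifs, main set, windows and most alternatives were chosen before the data were examined. The weak-peak limit of 60, the IDR alternatives of 0.05 and 0.001, the setting that puts absent peaks back, windows of 401 bp, 8-mers, the position and strand of ACAGTG, base composition around summits, and the replicate ratio by gene list with its pooled group of 4 lists were chosen after seeing the data. The design assumed an IDR threshold of 0.05 with 0.01 as a stricter alternative. The files were thresholded near 0.01 already, so that alternative is the same set and was not run, and 0.001 took its place.

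The gene list, motif, 6-mer, TSS share and replicate ratio steps were tested on simulated data, and the overlap, promoter signal, 8-mer, ACAGTG orientation and base composition steps were not. For gene lists over 13968 genes, 486 of 500 enriched lists of 20 or more members were recovered, with 9 calls among 737 unchanged lists. For motifs over 4099 windows, all 20 implanted motifs were recovered, with 1 call among 380 others, and for 6-mers all 25 were recovered, with 11 of 10375 others called. For the TSS share, all 1000 positions placed within 400 bp of a TSS were counted as within 500 bp, which their placement fixed. This checked the counting and not the permutation test. For the replicate ratio over 1700 peaks, 20 of 20 simulated shifts were recovered, with no calls in 20 runs without one. Settings varied were the TSS window, the TSSs used, the peak set, each replicate's own set, the overlap rule, matched random lists, motif window widths and GC-matched controls.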

Results

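Chromatin bound by Sequoia, the product of the gene seq, was mapped by ChIP-seq in whole Drosophila melanogaster embryos aged 0 to 24 h. Sequoia is a zinc finger protein known for its part in the growth of axons and dendrites. The embryos carried seq fused to enhanced GFP, and chromatin was precipitated with an antibody against GFP. The labels gave 2 biological replicates of 1 group and no other condition, so the comparisons made here were between the replicates and between bound and other parts of the genome. The measurements were lists of peaks on the dm6 build, with 4100 peaks in the conservative set made between the replicates, 4069 in the set of replicate 1 and 2680 in the set of replicate 2. Of the conservative peaks, 4099 lay on the chromosome arms 2L, 2R, 3L, 3R, 4 and X and are described below. Peak strength is the authors' signal value, which ranks peaks within a list. Read depth was not given in the sources used here, so the depth behind each peak is unknown.

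Sequoia peaks were concentrated at gene starts, were present in introns and between genes, and were scarce in coding exons and 3' untranslated regions. Of the 4099 summits, 1828 (44.6%, exact 95% interval 43.1 to 46.1) lay within 500 bp of an annotated transcription start site (TSS), against 13.6% for random positions on the same arms, a 3.29-fold excess. Most promoter summits, 1353 of the 1828 (74.0%), lay upstream of the nearest TSS, at a median offset of -110 bp. Introns held 37.6% of summits (random positions 39.5%) and intergenic sequence 14.8% (27.2%). Coding exons held 34 summits (0.829%, against 13.7%) and 3' untranslated regions 22 (0.537%, against 4.42%).

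The excess at TSSs had a one-sided permutation p = 0.0099, the smallest that 100 random placements can give. Among the annotation classes, the excess in promoters and the lower shares of coding exons, 3' untranslated regions, introns and intergenic sequence each had a two-sided permutation p = 0.0198, again the smallest possible. Shares add up to 100%, so the promoter excess by itself lowers the other shares. The small differences in introns and 5' untranslated regions thus do not show depletion outside promoters, where introns held 1542 of 2271 summits. The 5' untranslated regions outside promoters held 0.512% of summits against 0.810% (two-sided permutation p = 0.0396), and this call ended when ranked peaks absent from the conservative set were put back, at 0.569%. Noncoding exons held 1.15% against 0.810% (two-sided permutation p = 0.0792) and passed the test in that same setting, at 1.16%. Intervals on shares of peaks cover counting error only.

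Promoter peaks were also the stronger ones. The promoter share fell from 71.0% (61.1 to 79.6) of the 100 strongest peaks to 60.3% (55.3 to 65.1) of the next 400 and 38% (35.2 to 41.0) of ranks 3001 to 4099. The median signal was 128.7 for promoter peaks and 110.5 for all other peaks, a difference of 18.2 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; peaks are not replicates). In replicate 1's own set the difference was smaller, at 3.54 (two-sided permutation p = 0.00358), and in replicate 2's own set it was 11.7. Across arms, 2L held 32.5 peaks per Mb (exact Poisson interval 30.3 to 34.9), 2R 30.3, 3L 31.7, 3R 29.0 and X 31.5 (29.3 to 33.8). The small chromosome 4 held 12 peaks, 9.01 per Mb (4.66 to 15.7), and Y held none, for which 3 counts allow a density of up to 0.880 per Mb.

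**Figure D1:**
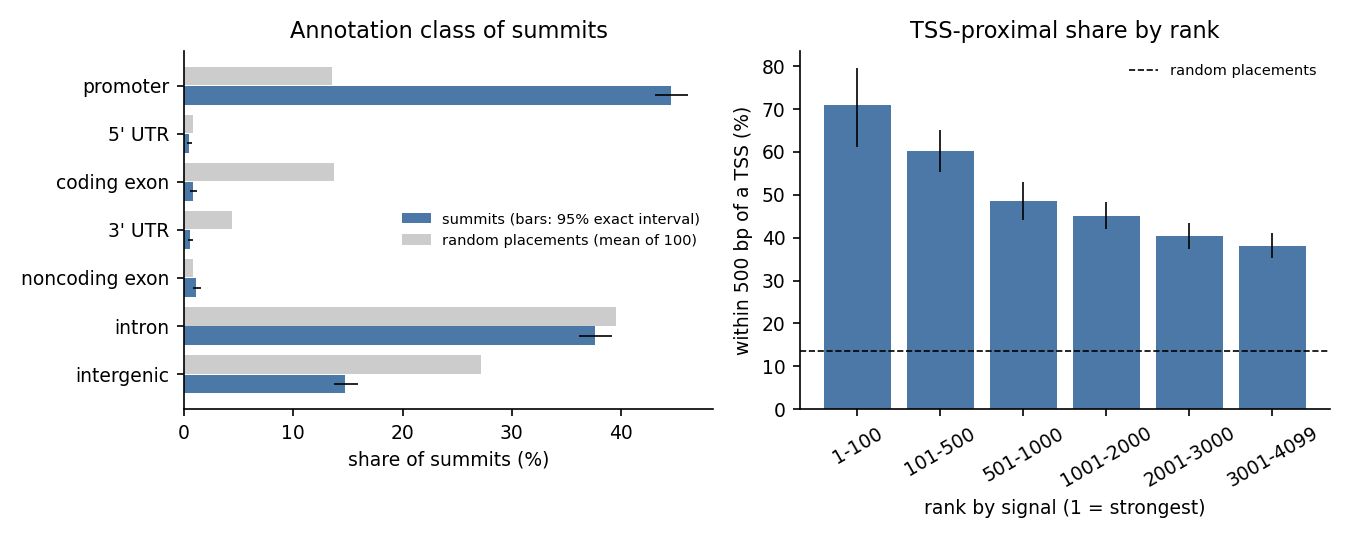
Left, share of the 4099 conservative summits in each annotation class (%, blue, with exact 95% intervals) and mean share over 100 random placements (grey). Right, share of summits within 500 bp of a TSS (%) by rank of the authors' signal, falling from 71.0% in the 100 strongest to 38% in ranks 3001 to 4099, with the random share of 13.6% dashed.

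The strongest promoter peaks of protein-coding genes were at Ugalt, CG14100 and Chro. That at Ugalt, a UDP-galactose transporter gene (X:2703708-2704062, summit 40 bp upstream of the TSS), was also the strongest peak of the conservative set, with a signal of 1655 there, 924 in replicate 1 and 730 in replicate 2. Among promoter peaks, CG14100 (3L:19590459-19590771, rank 3 of all peaks) followed with 1417, Chro (3L:22878742-22879062, rank 6), which encodes the chromatin protein Chromator, with 1185, CG18549 with 1146 and CenG1A with 1093. Some of the 20 strongest lay within 500 bp of a TSS of another gene too: Ssl1 for Chro, mRpS23 for CenG1A, Fbw5 for CG9147, mRpS10 for Art3, Mtl for CG5611, CHMP2B for Tcs5 and CIA30 for CG7601. Next came mRpL41, another mitochondrial ribosomal protein gene (1069), PNPase, a mitochondrial RNA processing enzyme gene (1062), eIF6, a translation initiation factor gene (1010), CG9147 (969) and ph-p, a Polycomb group gene (966). The rest of the 20 strongest were px, Tina-1, Art3, CG5611, RluA-1, Tcs5, SLC5A11, Fkbp14, gish and CG7601, with signals from 966 at px to 885 at CG7601. In these 20 genes the replicate values lay close together, with log2 ratios of replicate 1 to replicate 2 between -0.38 at Tcs5 and 0.40 at eIF6.

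Of all summits, 1271 (31.0%) lay over 2000 bp from any TSS. The strongest of these, rank 5 of all peaks, was intergenic at 2R:13035162-13035508, 11924 bp from the TSS of CG13323, with a signal of 1309 (652 in replicate 1 and 661 in replicate 2). The next 4 were in an intron of CG12769 (2R:8060855-8061176, signal 959), in an intron of Tlk, the gene of the Tousled-like kinase (X:3742077-3742347, 766), between genes 8380 bp from lncRNA:CR45695 (2L:1638614-1638962, 727) and in an intron of CG32486 (3L:3060668-3060939, 707). Some strong ranked peaks past the same IDR threshold were absent from the conservative set and enter none of these values, among them a peak in ush at 2L:480911-481268 (signal 1636) and peaks at Lk6 (1036) and larp (770).

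Among the gene lists fixed before the data were examined, genes of segmentation and of the cytoplasmic ribosome held promoter peaks most often, followed by neuronal identity and Hox genes at equal shares. Of all protein-coding genes, 1925 of 13968 (13.8%, 13.2 to 14.4) had a summit within 500 bp of a TSS. Segmentation genes, which divide the early embryo into segments, had one in 22 of 30 members (73.3%, 54.1 to 87.7). Examples were cad (2L:20770424-20770732, signal 749), ems (353) and btd (350), and eve, Kr, hb, run, en and nkd were among the other members with a peak. Cytoplasmic ribosomal protein genes had one in 27 of 50 members (54%, 39.3 to 68.2), led by RpL32 (3R:30046206-30046306, signal 343), RpL7 (275) and RpL30 (256.4). Neuronal identity transcription factor genes had one in 19 of 38 members (50%, 33.4 to 66.6), led by ap (2R:5726790-5727179, signal 232), tup (228) and unpg (223).

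The odds ratio against all other protein-coding genes was 17.4 for segmentation genes (two-sided Fisher's exact test, adjusted p = 3.4e-12 over 17 lists), 7.43 for ribosomal protein genes (adjusted p = 1.78e-10, exact) and 6.31 for neuronal identity transcription factors (adjusted p = 5.89e-07, exact). These 3 calls held under all 12 alternatives tried. Their size moved by over 1.5 times in some of them. In replicate 2's own set the odds ratio was 10.3 for segmentation genes and 3.66 for neuronal identity transcription factors, and in replicate 1's own set it was 11.6 for the latter. With only the 5'-most TSS it was 3.59 for neuronal identity transcription factors, with gene bodies plus 1000 bp it was 11.1 for these and 4.75 for ribosomal protein genes, and with a 200 bp window it was 11.3 for ribosomal protein genes. Against random lists matched on the number of TSSs and gene length, the fold was 4.55 for segmentation, 3.06 for ribosomal protein and 1.80 for neuronal identity genes. The ribosomal protein, heat shock and insulator lists had been included to test housekeeping and very active promoters. The random lists were not matched on expression or open chromatin, so signal that follows promoter activity in general cannot be told apart here.

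Lists of chromatin regulators and further developmental lists also held promoter peaks above the share of other genes. Polycomb and Trithorax group genes, which maintain on and off states of development genes, had a peak in 11 of 26 members, led by ph-p (966), brm (520) and E(z) (250), with an odds ratio of 4.61 (Fisher's exact test, adjusted p = 0.00148). Notch pathway and E(spl) complex genes had one in 9 of 22, led by gro (440), E(spl)m3-HLH (176) and mam (148), with an odds ratio of 4.35 (adjusted p = 0.00496, exact). Axon and dendrite guidance genes, the process in which Sequoia itself is known to act, had one in 12 of 35, led by trio (236), trn (199) and PlexA (196), with an odds ratio of 3.28 (adjusted p = 0.00496, exact). This call ended with only the 5'-most TSS (2.30), at an IDR of 0.001 (2.91) and against matched random lists (1.63-fold). Mesoderm and muscle genes had 11 of 33, led by tin (345), Msp300 (335) and Six4 (248.5), with an odds ratio of 3.14 (adjusted p = 0.00737, exact). Endoderm, gut and fat body genes had 8 of 23, led by cad, fkh (442) and bowl (434), with an odds ratio of 3.35 (adjusted p = 0.0156, exact). Insulator and housekeeping promoter factor genes had 7 of 16, led by Chro, Cp190 (387) and Dref (162), with an odds ratio of 4.88 (adjusted p = 0.00737, exact). The Dref peak is shared with RpL13 and counts for both genes.

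Hox genes, which set segment identity, had a promoter peak in 4 of 8 members: Dfd (3R:6791458-6791747, signal 463), Abd-B (190), Scr (165) and lab (149). Their odds ratio was 6.27 (Fisher's exact test, two-sided, adjusted p = 0.0246). Proneural, sensory organ precursor and neuroblast genes had 9 of 31, led by numb (424), Dr (383) and D (290), with an odds ratio of 2.57 (adjusted p = 0.0433, exact). Genes of the adult gonads and accessory glands, tissues not yet formed in embryos, had 0 of 36, for which 3 counts allow a share of up to 8.33% (odds ratio 0, adjusted p = 0.0134, exact). The calls of the proneural, Notch and Hox lists ended in replicate 2's own set, at odds ratios of 1.72, 1.99 and 2.98, as did that of the gonad list, still at 0, and that of the insulator list ended in replicate 1's own set, at 2.72. Of the 9 called lists other than the first 3 named, the Notch list (3.24-fold), the insulator list (2.54-fold) and the Polycomb and Trithorax list (2.05-fold) passed against the matched random lists, the last pair narrowly (two-sided permutation adjusted p = 0.0482 for each). The others lay between 1.36-fold (mesoderm and muscle) and 2.00-fold (proneural), with the gonad list at 0.

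Genes of differentiated neurons and glia did not stand out. Pan-neuronal differentiation genes had a promoter peak in 5 of 30 members, led by elav, an RNA-binding protein gene active in neurons (X:523343-523640, signal 627), fne (176) and Gad1 (151), with an odds ratio of 1.25 (two-sided Fisher's exact test, adjusted p = 0.597). Another member counted there, nSyb, had a signal of 18.8 only. Glial genes had 5 of 20, led by moody (399), Gli (189) and pnt (118), with an odds ratio of 2.09 (adjusted p = 0.206, exact), which passed in 4 alternatives such as a TSS window of 1000 bp (4.04). Heat shock and stress genes had 6 of 21, led by Hsp27 (466), Hsp83 (283) and Hsp26 (231), with an odds ratio of 2.51 (adjusted p = 0.0714, exact), which passed in each replicate's own set, at 4.48 (replicate 2) and 3.0 (replicate 1). Tracheal, epidermal and cuticle genes had 8 of 30, led by rib (280), cora (186) and trh (166), with an odds ratio of 2.28 (adjusted p = 0.0714, exact), which passed when gene bodies plus 1000 bp were searched (3.0). Adult eye phototransduction genes had 2 of 25, rdgC (361) and rdgB (84.1), with an odds ratio of 0.544 (adjusted p = 0.597, exact). Over the settings tried, odds ratios ranged from 0.827 to 3.0 for tracheal, 0.308 to 1.74 for pan-neuronal and 0.249 to 0.853 for adult eye genes.

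**Figure D2:**
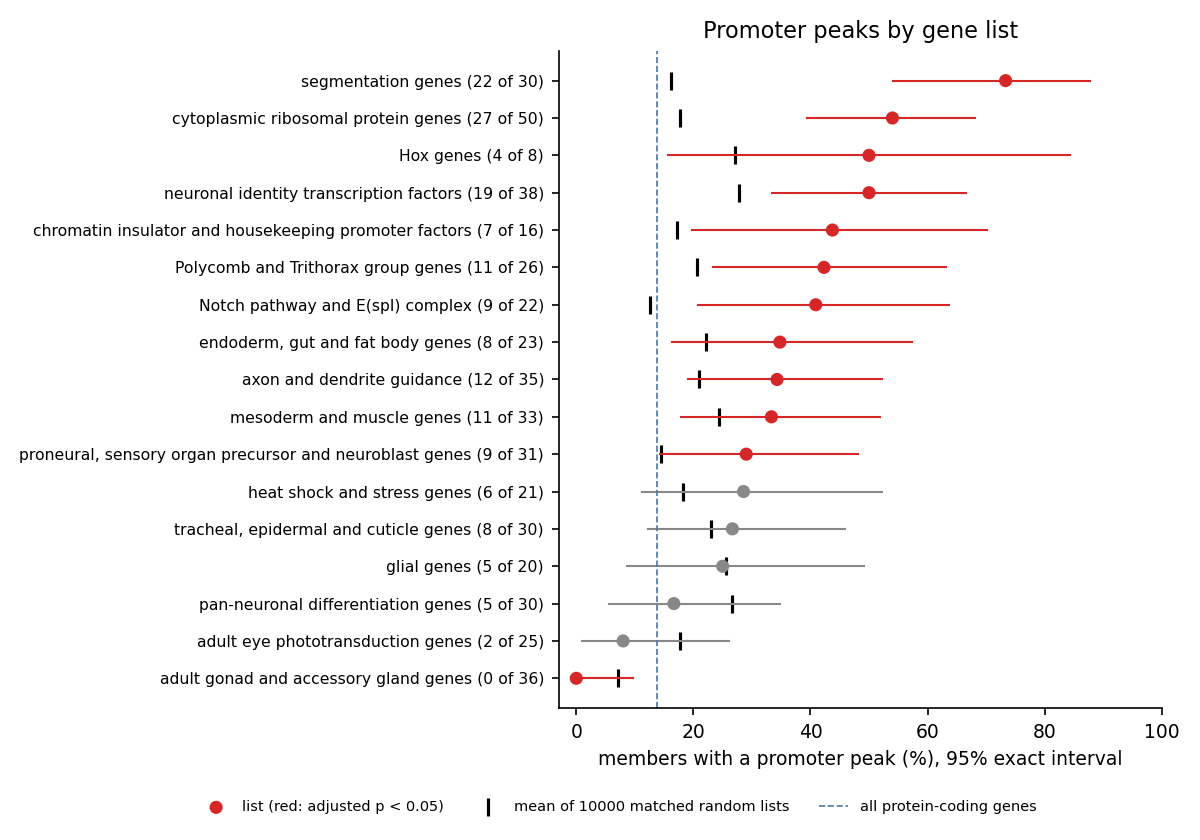
Share of the members of each gene list with a summit within 500 bp of a TSS (%, points, with exact 95% intervals; red where the adjusted p of Fisher's exact test passed 0.05), the mean of 10000 random lists matched on TSS number and gene length (black ticks) and the share of all protein-coding genes (13.8%, dashed). Segmentation genes lie furthest right at 73.3%, and adult gonad genes lie at 0 of 36.

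At the seq locus itself (2R:13176553-13190086, minus strand), conservative peaks lay within the gene and upstream of it, and replicate 2's own set held upstream ones only. The whole locus lies inside the annotated span of Kdm4B, a histone demethylase gene on the same strand. A TSS of Kdm4B shares the position of the seq TSS, so peaks near or upstream of it cannot be assigned to either gene. The strongest peak had its summit at 13192404, 2318 bp upstream of the seq TSS and in a Kdm4B intron, with a signal of 185.6, rank 948 of 4099. The next summit, at 13189382 (126.0), lay 704 bp into seq and 129 bp from a TSS of Kdm4B. Others lay at 13194327 (104.7, 4241 bp upstream) and at 13177598 (83.8, in a coding exon). The summit nearest the seq TSS, at 13190203 and 117 bp upstream (84.5), was in the set made from pooled replicates and in replicate 1's set (62.1), but not in the conservative set. Replicate 2's own set held 2 peaks here, at 13192397 (116.1) and 13194151 (55.3), and none within seq, and replicate 1's own set lacked the one at 13177598. Whether the seq fusion adds a further copy of this sequence to the genome was not tested here, and such a copy would add to signal over the gene.

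GA-rich sequence was more frequent at Sequoia summits than at control positions, and the E-box CAGGTG was less frequent. GAGAGA, the element bound by the GAGA factor Trl, was present in 304 of 4099 windows reaching 50 bp either side of the summit (7.42%) against 3.67% of control windows at the same offset from other TSSs or elsewhere on the arm. Its odds ratio was 2.10 (two-sided Fisher's exact test, adjusted p = 2.09e-22 over 20 motifs). CAGGTG, bound by the Snail and Scratch proteins, was present in 2.44% against 3.88%, an odds ratio of 0.619 (adjusted p = 1.99e-05, exact). These 2 motifs passed under all 12 alternatives. None of these matched controls on annotation class. Coding exons held 13.7% of random positions and 0.829% of summits, so a difference in class may enter these odds ratios.

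A further 6 motifs passed in the same test and lost that call elsewhere, the TATA box under all 12 alternatives and CAGCTG under 10: GATA (odds ratio 1.24), Su(Hw) (1.84), the CA repeat (1.47), the homeobox core TAATTA (1.21), the TATA box (1.32) and the proneural E-box CAGCTG (0.762). GATA and Su(Hw) lost it against controls matched on GC content, among other settings. The direction turned for CAGCTG in windows reaching 200 bp either side (1.30), for TAATTA against GC-matched controls (0.933), for the TATA box in replicate 1's own set (0.879) and for the CA repeat in replicate 2's own set (0.694). In the wider windows CAGCTG was thus more frequent at peaks, up to 1.33 with GC-matched controls. Its smallest adjusted p in any setting was 3.56e-10 (Fisher's exact test), against 0.00587 in the main test, where it was less frequent. The other 12 motifs did not pass: Zelda (0.855), DRE (0.650), Motif 1 (0.714), Ohler motif 6 (0.434), Initiator (0.902), Su(H) (0.712), Ttk69 (0.568), CTCF (1.21), AP-1 (1.48), ETS (0.900), Grainyhead (0.714) and STAT (0.953), all as odds ratios. Of these, Initiator passed in 6 of the 12 alternatives, CTCF in 5, and DRE, Su(H), AP-1, STAT, ETS, Ttk69 and Grainyhead in 1 to 3 each.

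Without assuming a motif, C-rich, GA-rich and AT-rich 6-mers were more frequent at summits. Of all 6-mers, 122 were more frequent and 137 less frequent both for peaks on 2L, 2R and X, where they were found, and for those on 3L, 3R and 4, which were held out. Controls of promoter peaks came from any arm in both parts. CACCCC had the smallest held-out p, in 7.11% of held-out peaks against 2.32% of controls (odds ratio 3.22, Fisher's exact test, two-sided, adjusted p = 1.74e-18). AGAGAG (8.15% against 3.67%, odds ratio 2.33) and ACAGTG (7.22% against 3.87%, odds ratio 1.93) also passed, as did AT-rich words such as TAAATA (24.7% against 16.2%). The words less frequent at summits included CCTGGA (1.04% against 3.29%, odds ratio 0.308). Here too, controls were not matched on annotation class. Against GC-matched controls the counts fell to 51 and 16, and CACCCC (3.79), ACAGTG (2.49) and AGAGAG (2.30) had odds ratios above 2, whereas TAAATA was no longer among the words kept.

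**Figure D3:**
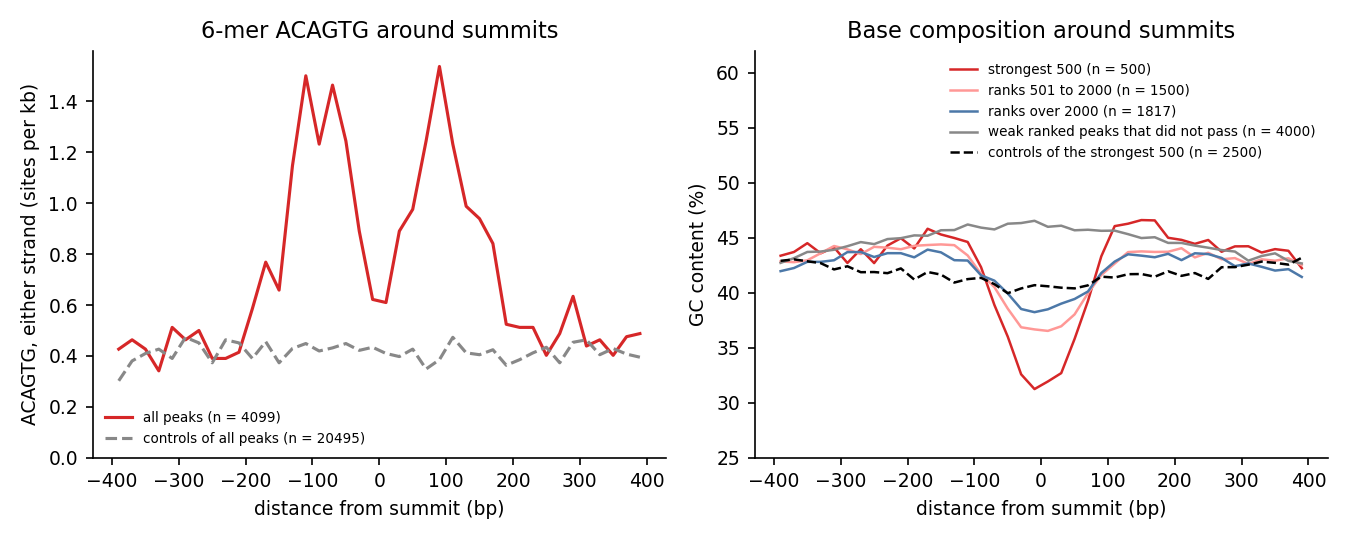
Left, sites of the 6-mer ACAGTG on either strand per kb by distance from the summit (bp) in 20 bp steps, for all 4099 peaks (red) and their controls (grey): sites rise to 1.54 per kb beside the summit and fall to 0.61 per kb at it. Right, GC content (%) by distance from the summit in the 500 strongest peaks, in weaker ranks, in weak ranked peaks that did not pass and in controls of the 500 strongest; flanks minus summit differ by 14.3 percentage points in the 500 strongest.

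The replicates shared most of their strongest peaks and differed in the number of peaks. The ratio of replicate 1 to replicate 2 signal rose with the GC content of peaks. It was also higher at promoter peaks of segmentation, neuronal identity and proneural genes than at other promoter peaks. Of the 100 strongest peaks of each replicate, 77 overlapped. Of replicate 1's 4069 peaks, 2068 (50.8%, 49.3 to 52.4) overlapped a peak of replicate 2, and of replicate 2's 2675 peaks on the arms, 2047 (76.5%, 74.9 to 78.1) overlapped one of replicate 1, against 1.32% and 1.95% for shuffled peaks. In the other replicate's ranked list before its threshold, 95.2% and 99.4% had an overlapping peak, against 42.3% and 40% for shuffled peaks. The rescue ratio of pooled to conservative peak numbers was 1.29, and the self-consistency ratio of the replicates' own peak numbers was 1.52. Across 4074 conservative peaks the 2 replicates' signals had a Pearson r of 0.710 on a log scale and a Spearman rho of 0.572. These values are across peaks, which are not independent replicates. The peaks had also passed an IDR threshold between the same replicates, which selects for agreement.

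Promoter peaks of segmentation and neuronal identity genes had more of their signal in replicate 1 than other promoter peaks had. This comparison was chosen after the values were seen and covered 14 gene lists with 5 or more peaks. Its permutations shuffled peaks, which are not replicates, within this pair of libraries. The p-values thus do not show whether a difference would recur in other collections. The median log2 ratio of replicate 1 to replicate 2 was 0.69 higher for 22 segmentation peaks (20 above the median of other promoters; two-sided permutation adjusted p = 0.0007) and 0.75 higher for 20 neuronal identity peaks (19 above; permutation adjusted p = 0.0007). It was 0.63 higher for 10 proneural peaks (9 above, permutation adjusted p = 0.0299), and the other 11 lists did not pass. Among those, it was 0.70 higher for 5 pan-neuronal peaks (4 above, permutation adjusted p = 0.098), 0.47 for endoderm and 0.44 for tracheal peaks. It was lower for axon guidance (-0.087), glial (-0.053) and insulator peaks (-0.23). GC content differed too, with a median of 52.4% in the promoter peaks of the segmentation, neuronal identity, proneural and Hox lists pooled and 39.9% in other promoter peaks. Their pooled difference of 0.71 fell to 0.33 within deciles of GC content. Across conservative peaks in general the ratio rose with GC content (Spearman rho 0.41), and the tests of single lists did not account for this. At cad the signal was 504 in replicate 1 and 238 in replicate 2, at ap 171 and 54.3, at unpg 168 and 55.7, and at Scr 118 and 43.8. At gro (209 and 237), brm (235 and 275) and elav (303 and 331) replicate 2 had the higher value. In the same list as elav, fne (105 and 66.8) and Gad1 (102 and 47.5) had the higher value in replicate 1.

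**Figure D4:**
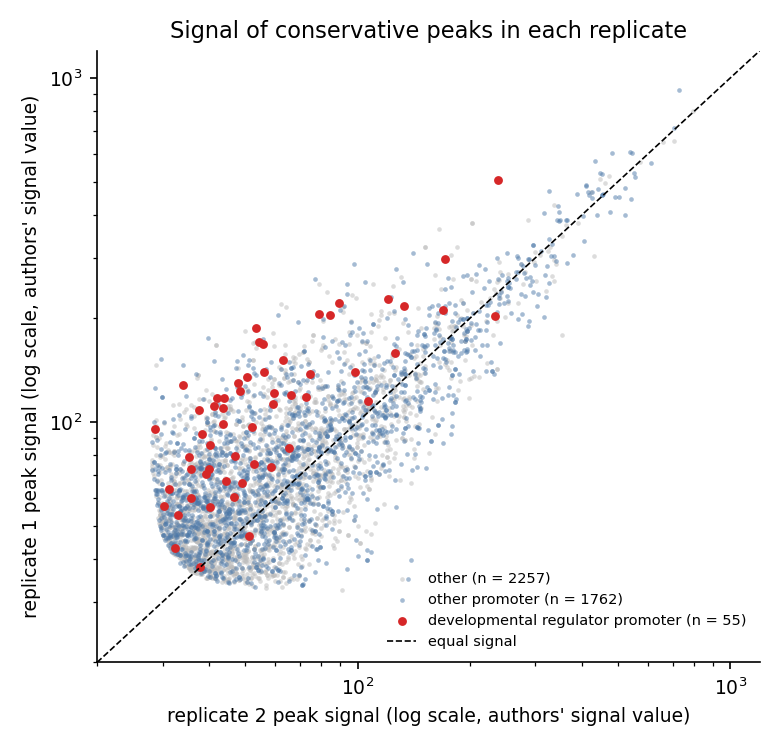
Signal of the strongest overlapping ranked peak in replicate 1 (y, log scale) and replicate 2 (x, log scale) for 4074 conservative peaks, with 55 promoter peaks of segmentation, neuronal identity, proneural and Hox genes in red, other promoter peaks in blue, the rest in grey and equal signal dashed. Most red points lie above the line of equal signal, with a median log2 ratio of 0.91 against 0.20 for other promoter peaks.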

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

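The tests of how far the absent peaks differed between the replicates, and the pooled group of developmental regulators, were chosen only after related values were seen.

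A signal lay outside the analysed set: 117 ranked peaks past the IDR threshold were absent from the conservative list, with 69 on 3R and 40 on 2L. These 2 arms held 93.2% of the absent peaks and 41.4% of the kept ones, and 5 of the 100 strongest ranked peaks were absent, including those in ush (signal 1636), at Lk6 (1036) and at larp (770). Removal of peaks that differ strongly between the replicates is argued against, since 7 absent peaks (6.09% of those with a signal in both replicates, exact 95% interval 2.48 to 12.1) lay beyond the 95th percentile of kept peaks of the same signal decile, while a small difference stays open (median absolute log2 ratio higher by 0.036, two-sided permutation p = 0.38). Removal of whole regions by the authors' filtering stays open. The 50 spans that join absent peaks less than 20 kb apart held 21 thresholded peaks of the 4 sets (18.8 at the genome's density). This was more than the 5 set beforehand as the limit, but the sets share loci, so these are 8 distinct loci in 5 spans. Of the 26 spans with several absent peaks, 3 held a thresholded peak. A span can be wider than what was removed, so that limit could not decide. No biological explanation was tested, since the design has 1 group.

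Promoter peaks of 4 developmental lists (segmentation, neuronal identity, proneural and Hox; 55 peaks) had a median log2 ratio of replicate 1 to replicate 2 of 0.91, against 0.20 in 1629 other promoter peaks (difference 0.71); 3 of the lists were pooled after they had shown this shift, so no p is given for it. A library size or number of called peaks that shifts all peaks of like signal equally is argued against. The difference within deciles of signal was 0.73, where that explanation needs it near 0. As 3 of the lists were picked for this shift, its size may be overstated. An effect of library size that differs between kinds of peak was not tested. GC content may account for part of the pooled difference. Across conservative peaks in general the ratio rose with GC content (Spearman rho 0.41). The developmental peaks had a median GC content of 52.4% against 39.9%, and within GC deciles the difference fell to 0.33, and what remains stays open. A different mix of embryo ages in the collections stays open and was not tested, and no biological explanation was tested.

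The 500 strongest summits were AT-rich between GC-richer flanks, with a GC content 14.3 percentage points lower in the central 21 bp than 100 to 200 bp away (bootstrap 95% interval 13.0 to 15.6), and the difference was 7.78 in the next 1500. The base composition of promoters in general is argued against, since strong peaks over 2000 bp from any TSS had a difference of 10.9 (7.23 to 14.4), and control windows at other promoters had 1.89. A GC bias shared by all called regions is argued against too, since weak ranked peaks that did not pass had a difference of -0.944. A bias that acts on strong peaks alone was not tested, and no biological explanation was tested.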

How the results depend on the processing

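The IDR threshold of 0.001, weak peaks left out, absent peaks put back, IDR 0.05, windows reaching 200 bp either side and the strongest overlapping ranked peak were chosen after seeing the data, and the planned IDR of 0.01 was not run because the files were already thresholded there. No paired analysis was possible because the design has 1 group. Of 535 values under alternatives, 400 kept their direction and their side of the threshold or range. The excess at TSSs passed in all its alternatives (39.3% to 56.2% of summits, 29.8% with a 200 bp window), and so did the higher signal of promoter peaks (3.54 to 22.2). The share of replicate 1 peaks in replicate 2 and of replicate 2 in replicate 1 moved to 43.2% and 65.4% with 0.5 reciprocal overlap, 45.8% and 69.6% with summits within 100 bp, and 64.3% and 67.7% with equal numbers of peaks, and the first moved to 57.7% at IDR 0.001. Pearson r and Spearman rho moved to 0.727 and 0.598 with weak peaks left out and to 0.751 and 0.610 with the strongest overlapping peak. With absent peaks put back, the lower share of 5' untranslated regions no longer passed (0.569%) and the excess in noncoding exons did (1.16%). At IDR 0.001, with fewer peaks, 1110 genes had a promoter peak, and 4 lists and 5 motifs passed. List odds ratios that no longer passed there were 2.91 (axon guidance), 2.79 (proneural), 2.58 (Notch), 3.23 (endoderm), 6.97 (Hox), 2.77 (Polycomb and Trithorax), 3.87 (insulator) and 0 (gonad). With only the 5'-most TSS, 7 lists passed, and axon guidance (2.30), proneural (1.86), endoderm (2.74), Hox (4.65) and gonad (0) did not. With a 200 bp window, Notch (2.10), endoderm (2.63), Hox (5.67) and gonad (0) no longer passed. Against matched random lists 6 passed, and the folds that did not were axon guidance 1.63, proneural 2.00, mesoderm 1.36, endoderm 1.57, Hox 1.85 and gonad 0. Lists that came to pass were glial and heat shock with a 1000 bp window (4.04, 3.04), with gene bodies plus 1000 bp (3.42, 2.56) and in the pooled set (3.93, 2.96), and tracheal with gene bodies (3.0). In the sets of single replicates, lists ranged over 1.72 to 4.96 (proneural), 1.99 to 5.01 (Notch), 2.98 to 18 (Hox), 2.72 to 6.98 (insulator), 0.993 to 3.23 (glial), 3.0 to 4.48 (heat shock) and 0 in both (gonad, no longer passing without replicate 1). Over all settings, other lists not called ranged over 0.308 to 1.74 (pan-neuronal), 0.827 to 3.0 (tracheal) and 0.249 to 0.853 (adult eye). Motifs that passed numbered 5 with GC-matched controls and 5 without either replicate. Motif odds ratios that turned were TAATTA with GC-matched controls (0.933), in windows reaching 200 bp either side (0.95) and in these GC-matched (0.968), CAGCTG at IDR 0.05 (1.00), in windows reaching 200 bp either side (1.30) and in these GC-matched (1.33), Grainyhead in GC-matched windows reaching 200 bp either side (1.65) and the CA repeat at IDR 0.001 (0.917). Without each replicate in turn, motifs ranged over 0.694 to 2.02 (CA repeat), 0.801 to 1.11 (CAGCTG), 0.879 to 1.27 (TATA box) and 0.922 to 1.51 (TAATTA). Words kept in both genome parts numbered 51 higher and 16 lower with GC-matched controls, 246 and 304 in windows reaching 200 bp either side, and 234 and 305 in these GC-matched. Except where fewer peaks were used, the cause of these changes was not tested. Read depth, which limits how many peaks each replicate can give, is unknown.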

Other observations

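The tests of the side of the summit on which ACAGTG lies, of 8-mers and of weak peaks were chosen only after related values were seen, and the other 2 tests were set down before their result.

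The 6-mer ACAGTG lay most often beside the summits of Sequoia peaks, and there in a preferred orientation. Sites from 40 bp to under 140 bp from the summit numbered 252 per 1000 peaks against 84.4 per 1000 controls, and sites under 40 bp from it numbered 58.8 against 33.1. The summit lay on the 3' side of the word at 747 of the 1032 sites from 40 bp to under 140 bp away (72.4%, 69.5 to 75.1, two-sided exact binomial p = 2.54e-48), against 50.9% of control sites. Sites are not all independent, since 1 window can hold several and 292 conservative peaks overlapped the next one. The interval and p thus overstate the certainty. At closer sites the share was 59.3% (controls 48.2%), and from 140 to 200 bp it was 60.9%, where controls also lay above 50%, at 54.7%. Within 200 bp of the summit the word was present in 29.6% of promoter peaks (controls 16.1%) and in 27.9% of peaks over 2000 bp from any TSS (controls 13.9%). In the 1000 strongest peaks, 224 8-mers were more frequent than in controls on 2L, 2R and X, of which 137 passed again on 3L, 3R and 4 and 11 of those held ACAGTG. The smallest held-out p belonged to the GA-rich GAGAGAAA (12.5% against 1.76%, odds ratio 7.98), and CACAGTGG was present in 9.95% of held-out peaks against 1.30% of controls (odds ratio 8.42).

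ACAGTG may mark the stronger peaks: it was present in 342 of the 1000 strongest and 278 of the 1000 weakest peaks with a signal of 60 or more, an odds ratio of 1.35 (two-sided Fisher's exact test, p = 0.00231), as predicted. This was not particular to ACAGTG, since AGAGAG was present in 38% of the strongest and 25.5% of the weakest. Peaks at ribosomal protein promoters could carry the same words as other promoter peaks, and this stays open: ACAGTG or AGAGAG was present in 10 of 28 ribosomal protein promoter peaks and 904 of 1656 others, an odds ratio of 0.462 (two-sided Fisher's exact test, p = 0.0556).

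A group of 282 conservative peaks (6.88%) had signals under 60, and 237 of them (84.0%, 79.2 to 88.1) lay within 400 bp of a stronger peak, against 0.763% of weak ranked peaks that did not pass and 1.98% of other peaks below the median signal. The promoter peak counted for nSyb (18.8) and that for sdt (12.6) belong to this group.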
